A study of Homo sapiens
Mus musculus with 16 samples.

How the data were processed

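ScaBER is an established human bladder squamous carcinoma cell line. Tumours grown from it in athymic nude mice were sequenced after 14 days of vehicle, nintedanib at 40 mg/kg, alpelisib (BYL719) at 25 mg/kg, or both drugs, with 4 libraries in each of the 4 groups and 16 libraries in all. Nintedanib inhibits VEGF, PDGF and FGF receptor kinases, and alpelisib inhibits the alpha isoform of PI3K. Libraries were made with a kit that reads the 3′ ends of polyadenylated RNA, and reads were mapped separately to the human and the mouse genome, so that transcripts of the tumour cells and of the host could be counted apart. Per the labels, TopHat was used with the builds hg19 and mm10. The counting tool, the gene annotation and the way libraries were scaled are not given in the sources used here. Genes were taken by the symbols in the tables, and no coordinates are given because the annotation at hand is of another build.

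The deposited tables hold signal, a normalized expression value per gene and library. In each library every value above 0 was a whole multiple of 1 step, within a tolerance of 0.01 read (100% of values), so the authors had divided whole reads by 1 size factor per library, and whole reads could be recovered. Recovered reads ran from 8303617 (nintedanib 4) to 18568119 (combination 2) in the human table and from 3606008 (vehicle 4) to 6850491 (combination 2) in the mouse table. The tables listed 23368 human and 23337 mouse genes, of which 20751 and 21202 had a read in some library. Reads of 3′ libraries without molecular identifiers are not independent molecules, so depth gives counting error only.

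The plan made before the data were examined assumed counts and set out a branch for normalized values, and the second branch was followed. Values were analysed as log2(value + 1). Genes with a value of at least 1 in at least 4 libraries were kept, which left 17663 human and 17484 mouse genes. A model with 1 mean for each of the 4 groups was fitted to all 16 libraries of a species with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3. In each species 6 comparisons were planned, namely each drug and the combination against vehicle, the combination against each drug, and the interaction (combination minus nintedanib minus alpelisib plus vehicle). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The labels give replicate numbers but not what a shared number means, nor whether each library came from its own animal, so p-values measure the spread between these samples.

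Gene lists, 22 for human and 26 for mouse, were also fixed before the data were examined. They cover signalling, growth, metabolism, stress and differentiation in the tumour cells, and vessel, stromal, immune and neighbouring host cell types in the mouse. Each list was tested with camera at its preset correlation of 0.01, adjusted over the lists of a species within a comparison. Camera with a correlation estimated from the data, and fry, were run beside it. For each list the members past the threshold were counted over all genes tested and when adjusted over the list alone. A list score was the mean over members of log2(value + 1), set to 0 at the vehicle mean. Named genes followed a rule written before the data were examined. It takes genes past the threshold with separated groups and at least median expression, up to 4 members of each list with the smallest p, for the interaction the 5 genes with the smallest p, and the drug targets. List scores and the share of mouse reads among all mapped reads were compared with vehicle by 2-sided exact permutation tests. Their smallest p with 4 against 4 libraries is 0.0286.

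The steps were tested on simulated data, in which 100 genes were moved by log2 1 and 100 by log2 2 in the combination group. Of these, 62 and 100 were recovered among human genes and 26 and 88 among mouse genes. Unchanged genes made up 6.25% and 5.74% of the calls, and a comparison with nothing changed gave 0 calls in both species. The moved genes were taken from those at or above median expression. Simulated genes were drawn independently of each other, so host tissue that moves many genes together was not simulated. These shares therefore do not give the rate of false calls in the real libraries.

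Alternatives planned were quantile normalization, limma without the trend, no filter on low values, a pseudocount of 0.1, replicate number as a block, leaving out genes whose human and mouse values were correlated, only the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma-voom on recovered reads, scaling to the human plus mouse total, a value of at least 10, omitting the 2 libraries rich in skeletal muscle transcripts, and muscle and fat scores as covariates. The effect of each drug averaged over both levels of the other drug was also added after seeing the data. No sample was left out of the main comparisons. A result for 1 gene that the rule would name is not reported here.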

Results

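Human-mapped and mouse-mapped transcripts were measured in 16 libraries of ScaBER tumours, 4 each from tumours given vehicle, nintedanib, alpelisib or both drugs for 14 days. The stated purpose was to learn what underlies the synergism of the drugs in vivo, in the tumour and in its stroma. Depth was 8303617 to 18568119 human reads and 3606008 to 6850491 mouse reads per library. The most abundant gene took 2.34% to 6.33% of human reads and 2.84% to 15.8% of mouse reads. Mouse reads made up 22.2% ± 2.10 (SD, n = 4) of all reads with vehicle, 26.0% ± 5.42 (SD, n = 4) with nintedanib, 26.0% ± 3.65 (SD, n = 4) with alpelisib and 27.4% ± 5.03 (SD, n = 4) with both. These shares did not differ detectably from vehicle, with exact permutation p of 0.257, 0.143 and 0.143. Without alpelisib 1 the alpelisib difference was 5.53 percentage points, and without combination 4 the combination difference was 7.47 points, each with an exact permutation p of 0.0286. The nintedanib difference fell to 1.155 points without nintedanib 4 (exact permutation p = 0.486).

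Libraries differed in the host tissue they carried. Transcripts of skeletal muscle took 5.25% of mouse reads in nintedanib 4 and 3.36% in combination 1, with list scores of 6.61 and 5.96 (log2, vehicle mean 0). Adipocyte scores were 3.92 in vehicle 1, 2.87 in alpelisib 2, 3.65 in alpelisib 4 and 1.95 in combination 2. The score of skin epithelium and hair was 5.63 in alpelisib 1 and between 0.14 and 0.72 in the other alpelisib libraries.

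**Figure D1:**
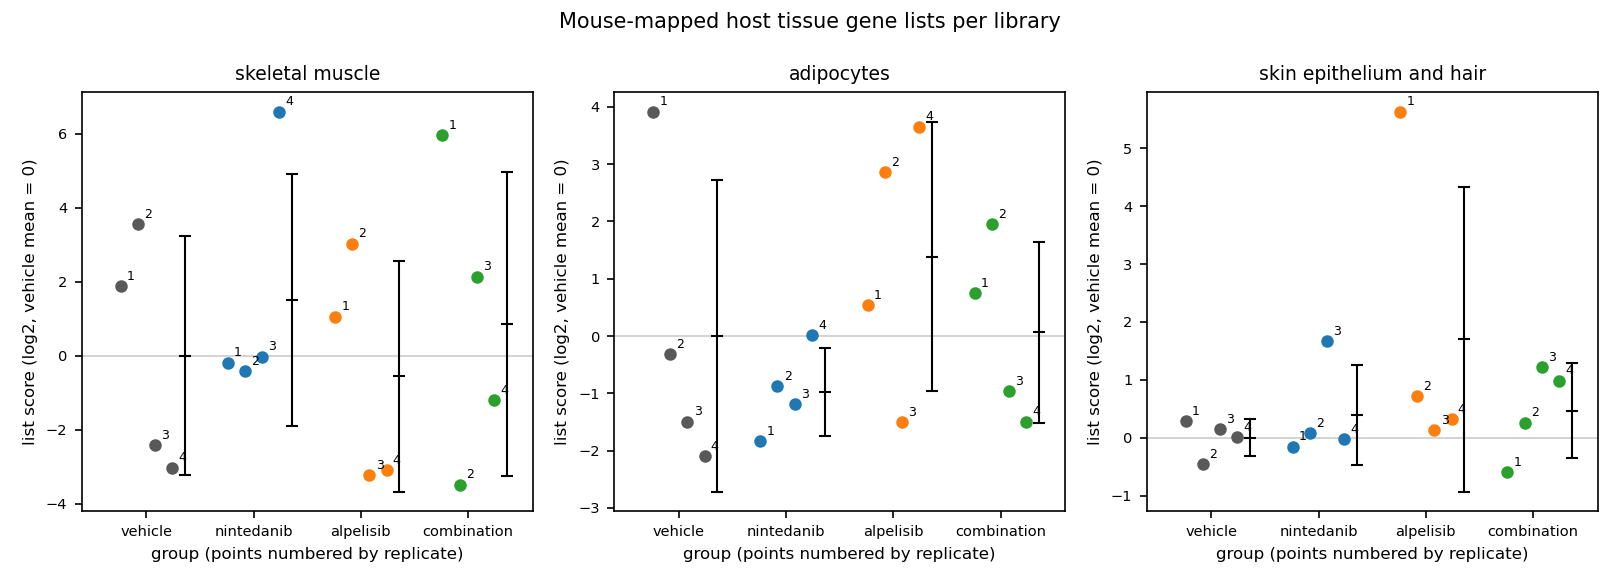
Scores of 3 host tissue gene lists in each mouse-mapped library (log2, vehicle mean 0). Points are libraries numbered by replicate, and black bars give group means ± SD (n = 4). Muscle scores were 6.61 in nintedanib 4 and 5.96 in combination 1, and the skin score was 5.63 in alpelisib 1.

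In the tumour cells, nintedanib alone went with more transcript of squamous differentiation and hypoxia genes and less of DNA replication and respiratory chain genes. The squamous differentiation list rose by a median log2 of 0.70, with 27 of 33 members above 0 and 14 higher when adjusted over the list alone (adjusted p = 1.74e-08, limma camera; adjusted p = 0.293 with an estimated correlation). Its members included CDSN, which encodes the corneodesmosome protein corneodesmosin (1.64, SE 0.35, adjusted p = 0.131 over all genes), the skin protease KLK7 (1.57, SE 0.33) and the cornified envelope precursor SPRR2A (1.78, SE 0.39). The hypoxia response list rose by 0.63, with 21 of 22 members above 0 and 2 higher when adjusted over the list alone (adjusted p = 1.16e-06; adjusted p = 0.483 with an estimated correlation), among them the mitophagy receptor BNIP3L (0.91, SE 0.29) and the MYC antagonist MXI1 (0.87, SE 0.26). Its median was 0.32 without vehicle 2 and 0.41 without nintedanib 1. The DNA replication and E2F target list fell by 0.38, with 10 of 22 members lower when adjusted over the list alone (adjusted p = 2.43e-07; adjusted p = 0.293 with an estimated correlation), including the replicative helicase subunits MCM2 (-0.69, SE 0.22) and MCM7 (-0.62, SE 0.19). Oxidative phosphorylation fell by 0.38, with 21 of 23 members below 0 and 2 lower when adjusted over the list alone (adjusted p = 4.73e-08; adjusted p = 0.293 with an estimated correlation). ATP5B of the ATP synthase stood at -0.60 (SE 0.16). Against vehicle, list scores had an exact permutation p of 0.0571 for squamous differentiation and 0.171 for hypoxia. It was 0.0286 each for DNA replication and oxidative phosphorylation.

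Mitotic genes of the tumour cells also fell with nintedanib, while FOXO targets were higher. Cell cycle and mitosis fell by 0.16, with 2 of 22 members lower when adjusted over the list alone (adjusted p = 0.00423; adjusted p = 0.483 with an estimated correlation), by 0.089 without vehicle 2 and by 0.24 when scaled to the human plus mouse total. The mitotic regulators FOXM1 and AURKB stood at -0.78 (SE 0.20) and -0.81 (SE 0.22). FOXO targets that PI3K inhibition raises were higher by 0.33 in 19 of 22 members, with 0 past the threshold when adjusted over the list alone (adjusted p = 0.000331; adjusted p = 0.293 with an estimated correlation). The ubiquitin ligase FBXO32 stood at 0.73 (SE 0.25) and the death ligand TNFSF10 at 0.75 (SE 0.28). Inflammatory NF-kB targets rose by 0.53, with 1 higher when adjusted over the list alone (adjusted p = 0.0121; adjusted p = 0.483 with an estimated correlation), a call lost without nintedanib 3 (0.15, adjusted p = 0.813), with medians of 0.32 and 0.33 without nintedanib 2 or vehicle 4. The iron-binding lipocalin LCN2 went from 132 ± 54.9 (SD, n = 4) with vehicle to 530 ± 132 (SD, n = 4) with nintedanib (log2 2.05, SE 0.38, adjusted p = 0.124). The receptor genes FGFR1, FGFR2 and FGFR3 gave -0.72 (SE 0.58), -0.12 (SE 0.21) and -0.33 (SE 0.20), and PIK3CA gave 0.70 (SE 0.37), none past the threshold, and FGFR2 gave 0.0096 without vehicle 2. With limma 0 of 17663 genes passed the threshold, while 2045 had an unadjusted p under 0.05 where chance gives 883. edgeR and limma-voom also gave 0 genes, and DESeq2 gave 74. In limma with only the 2 groups compared 89 genes passed, 83 of them higher, and without the 2 muscle-rich libraries 8 did, while limma without the trend and no filter on low values each gave 1. The count was 2 without vehicle 2, nintedanib 1 or combination 2, and 4 without alpelisib 4.

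Alpelisib alone went with more squamous differentiation, interferon response and antigen presentation transcript in the tumour cells. The squamous list rose by 0.49, with 29 of 33 members above 0 and 1 higher when adjusted over the list alone (adjusted p = 3.47e-14; adjusted p = 0.343 with an estimated correlation). CDSN stood at 1.34 (SE 0.35), the cornified envelope gene LCE3D at 1.20 (SE 0.38) and SPRR2A at 1.20 (SE 0.39). All 25 members of the interferon response list were above 0, by a median of 0.33, with 0 past the threshold when adjusted over the list alone (adjusted p = 1.21e-09; adjusted p = 0.396 with an estimated correlation), including IFIT3 (0.48, SE 0.23) and BST2 (0.42, SE 0.19), both antiviral genes. The score of this list was 0.69 in alpelisib 3 and 0.19 to 0.25 in the other alpelisib libraries, and without alpelisib 3 its median was 0.17. All 21 antigen presentation genes were above 0, by 0.27, with 0 past the threshold when adjusted over the list alone (adjusted p = 0.00047; adjusted p = 0.425 with an estimated correlation), such as the immunoproteasome subunit PSMB9 (0.34, SE 0.21) and the peptide transporter TAP1 (0.24, SE 0.17). That median was 0.16 without alpelisib 3. Glycolysis fell by 0.20 in 16 of 20 members, with 0 lower when adjusted over the list alone (adjusted p = 0.0162; adjusted p = 0.734 with an estimated correlation). That call was lost without vehicle 1, vehicle 3 (-0.018), vehicle 4, alpelisib 1, alpelisib 2 or alpelisib 4, and the median was -0.39 without vehicle 2.

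Lists tied to the drug's pathway moved little with alpelisib. FOXO targets rose by 0.13 in 15 of 22 members (adjusted p = 0.0454; adjusted p = 0.425 with an estimated correlation). TXNIP stood at 0.39 (SE 0.19) and the PI3K inhibitor protein PIK3IP1 at 0.40 (SE 0.20). That call was lost without vehicle 1 (0.019, adjusted p = 0.447), vehicle 2 (0.052, 0.378), alpelisib 1 (0.11, 0.115), alpelisib 3 (0.13, 0.303), nintedanib 1 (0.052), nintedanib 2 (0.0523), nintedanib 4 (0.0511) or combination 3 (0.0507, each an adjusted p), and the median was 0.087 without alpelisib 4 and 0.083 (adjusted p = 0.0647) when scaled to the human plus mouse total. ERK pathway output fell by 0.10 in 14 of 22 members (adjusted p = 0.00681; adjusted p = 0.425 with an estimated correlation). The ERK phosphatase DUSP6 stood at -0.53 (SE 0.20) and the immediate early gene EGR1 at -0.63 (SE 0.26). This list was no longer called without vehicle 3 (-0.036, adjusted p = 0.0862) or alpelisib 4 (-0.028, adjusted p = 0.216), and stood at -0.22, -0.20 and -0.26 without vehicle 2, alpelisib 2 or alpelisib 3. Cell cycle and mitosis fell by 0.12 in 18 of 22 members (adjusted p = 0.00681; adjusted p = 0.425 with an estimated correlation), a call lost without alpelisib 3 (-0.047, adjusted p = 0.137) or vehicle 2 (adjusted p = 0.0788). No member of these 3 lists passed when adjusted over the list alone or over all genes. LCN2 stood at 1.62 (SE 0.38, adjusted p = 0.986), PIK3CA at 0.09 (SE 0.37), FGFR1 at 0.55 (SE 0.58), FGFR2 at 0.31 (SE 0.21) and FGFR3 at 0.21 (SE 0.20), and PIK3CA stood at -0.055 without vehicle 1. By limma 0 genes passed, 438 had an unadjusted p under 0.05 where chance gives 883, edgeR and limma-voom gave 0 and DESeq2 gave 1. The count was 1 without combination 1 or combination 2, and 2 with only the 2 groups compared.

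Both drugs together went with less mitotic transcript and more hypoxia transcript in the tumour cells. All 22 cell cycle and mitosis genes were lower than with vehicle, by a median of -0.48, and 11 were lower when adjusted over the list alone (adjusted p = 2.94e-13; adjusted p = 0.130 with an estimated correlation). They included the mitotic kinesin KIF20A (-0.85, SE 0.23), the anaphase activator CDC20 (-0.72, SE 0.20), the mitotic kinase PLK1 (-0.89, SE 0.26) and the ubiquitin-conjugating enzyme UBE2C (-0.49, SE 0.15). The list score lay below all vehicle libraries in 3 of the 4 combination libraries and at -0.043 in the other. All 22 hypoxia genes were higher, by 0.65, and 5 were higher when adjusted over the list alone (adjusted p = 6.51e-10; adjusted p = 0.400 with an estimated correlation), including the vasodilator peptide ADM (1.01, SE 0.33), the angiogenic factor VEGFA (0.69, SE 0.23) and the collagen cross-linking enzyme LOX (1.14, SE 0.39). Without vehicle 2 the list median was 0.39, ADM stood at 0.62 and LOX at 0.67. Ribosome biogenesis fell by 0.30 in 19 of 20 members, with 0 lower when adjusted over the list alone (adjusted p = 9.99e-07; adjusted p = 0.393 with an estimated correlation). The assembly factor PES1 stood at -0.61 (SE 0.22). Mesenchymal genes rose by 0.35, with 1 higher when adjusted over the list alone (adjusted p = 0.000313; adjusted p = 0.393 with an estimated correlation). The actin-binding TAGLN stood at 1.25 (SE 0.30) and fibronectin, FN1, at 1.28 (SE 0.59). The call did not hold without vehicle 2 (0.15, adjusted p = 0.104), where FN1 stood at 0.41. Against vehicle, list scores had an exact permutation p of 0.0571 for cell cycle and mitosis and 0.171 for hypoxia. It was 0.0857 each for ribosome biogenesis and mesenchymal genes.

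Oxidative phosphorylation also fell with both drugs, by 0.26 in 17 of 23 members (adjusted p = 0.000286; adjusted p = 0.400 with an estimated correlation). Antigen presentation fell by 0.23 in 18 of 21 members (adjusted p = 0.000848; adjusted p = 0.438 with an estimated correlation), and neither list had a member past the threshold when adjusted over the list alone. Both calls were lost without combination 4 (-0.14 for each, adjusted p = 0.0753 and 0.126), and antigen presentation stood at -0.38 without combination 1. FOXO targets rose by 0.20 in 18 of 22 members (adjusted p = 0.0109; adjusted p = 0.400 with an estimated correlation). CITED2 stood at 0.70 (SE 0.23) and KLF9 at 0.81 (SE 0.32). As a list it lost its call without vehicle 1 (0.12, adjusted p = 0.115), vehicle 2 (0.13, adjusted p = 0.121) or combination 4 (0.16, adjusted p = 0.0634). ETV4 and EGR1, both read as outputs of ERK signalling, gave -0.71 (SE 0.22) and -0.82 (SE 0.26). PIK3CA gave 0.30, FGFR1 0.13, FGFR2 -0.02 and FGFR3 -0.09, none past the threshold. Their signs turned with single libraries left out, to -0.16 for PIK3CA without combination 4, -0.15 and -0.11 for FGFR1 without vehicle 1 or vehicle 3, 0.11 and 0.12 for FGFR2 without vehicle 2 or combination 3, and 0.056 for FGFR3 without combination 1. In limma, 0 genes passed, 1441 had an unadjusted p under 0.05, edgeR and limma-voom gave 0 and DESeq2 gave 14. The squamous list was not called (0.16, adjusted p = 0.404) but was without vehicle 2 (0.32, adjusted p = 0.0213) or combination 1 (0.36, adjusted p = 0.0113), and stood at -0.00034 without combination 2. The count of lists called was 11, and 6 without combination 4.

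Set against nintedanib alone, the combination had less squamous differentiation and mitotic transcript in the tumour cells. The squamous list fell by 0.60, with 27 of 33 members below 0 and 7 lower when adjusted over the list alone (adjusted p = 5.43e-08; adjusted p = 0.769 with an estimated correlation), and cell cycle and mitosis fell by 0.27 in 17 of 22 members with 0 lower when adjusted over the list alone (adjusted p = 0.000538; adjusted p = 0.769 with an estimated correlation), and by 0.47 without combination 1. Without the 2 muscle-rich libraries the medians were -0.37 and -0.41. The limma count was 0, 1638 had an unadjusted p under 0.05, edgeR and limma-voom gave 0 and DESeq2 gave 2. Without combination 4 the count was 136, of which 126 were lower.

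Set against alpelisib alone, the combination had more hypoxia transcript and less antigen presentation, interferon, squamous and mitotic transcript. KLK10, a secreted kallikrein protease of squamous epithelium, was the 1 gene past the threshold and fell from a normalized value of 1604 ± 146 (SD, n = 4) with alpelisib to 734 ± 141 (SD, n = 4) with both drugs (log2 -1.14, SE 0.18, adjusted p = 0.0486). All 22 hypoxia genes were higher, by a median of 0.74, and 7 were higher when adjusted over the list alone (adjusted p = 1.56e-12; adjusted p = 0.290 with an estimated correlation). Antigen presentation fell by 0.46, with 9 of 21 members lower when adjusted over the list alone (adjusted p = 5.33e-09; adjusted p = 0.247 with an estimated correlation), and all 22 cell cycle and mitosis genes were lower, by -0.34, with 0 lower when adjusted over the list alone (adjusted p = 2.20e-07; adjusted p = 0.247 with an estimated correlation). Interferon response fell by 0.29 in 24 of 25 members (adjusted p = 2.20e-07; adjusted p = 0.298 with an estimated correlation), squamous differentiation fell by 0.49 in 27 of 33 (adjusted p = 6.86e-06; adjusted p = 0.364 with an estimated correlation) and mesenchymal genes rose by 0.52 in 17 of 19 (adjusted p = 1.34e-05; adjusted p = 0.247 with an estimated correlation), each with 0 members past the threshold when adjusted over the list alone. The hypoxia median was 0.48 without combination 4, the cell cycle median -0.23 without combination 2 and the interferon median -0.44 without combination 1. The KLK10 call had an adjusted p between 0.0537 and 0.363 in the alternatives that ended it, among them leaving out any 1 library except nintedanib 1, nintedanib 4 or combination 2. edgeR and limma-voom gave 0 genes, DESeq2 gave 17, and limma without the 2 muscle-rich libraries gave 14.

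The interaction asks whether the drugs together differ from the sum of their separate effects. Squamous differentiation was, of the 22 tumour cell lists, the one with the largest median departure, at a median of -1.07, with 31 of 33 members below 0 and 13 lower when adjusted over the list alone (adjusted p = 3.64e-17; adjusted p = 0.202 with an estimated correlation). The list score was 0.58 ± 0.28 (SD, n = 4) with nintedanib, 0.51 ± 0.37 (SD, n = 4) with alpelisib and 0.09 ± 0.39 (SD, n = 4) with both. Interferon response stood at -0.30 in 24 of 25 members with 0 lower when adjusted over the list alone (adjusted p = 1.92e-05; adjusted p = 0.599 with an estimated correlation), and at -0.14 without alpelisib 3. The 5 genes with the smallest p were the collagenase MMP13 (-1.98, SE 0.36), CDSN (-2.52, SE 0.49), KLK10 (-1.34, SE 0.26) and the cornified envelope genes SPRR2G (-2.53, SE 0.51) and SPRR2E (-2.66, SE 0.54), each with an adjusted p of 0.205. Without the 2 muscle-rich libraries the squamous median was -0.70. With limma 0 genes passed, 1100 had an unadjusted p under 0.05, edgeR and limma-voom gave 0 and DESeq2 gave 10. The count was 3 without nintedanib 1 and 8 without combination 2.

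**Figure D2:**
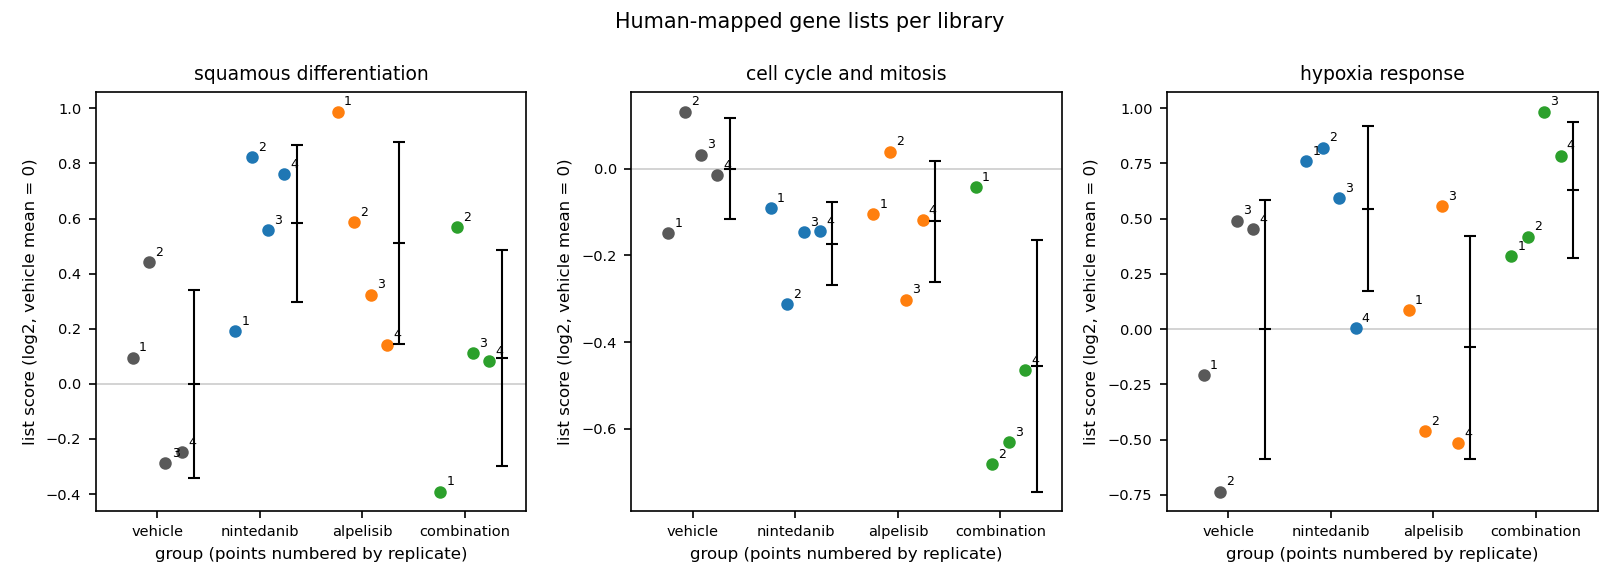
Scores of human-mapped gene lists in each library (log2, vehicle mean 0). Points are libraries numbered by replicate, and black bars give group means ± SD (n = 4). The squamous differentiation mean was 0.58 with nintedanib, 0.51 with alpelisib and 0.09 with both drugs.

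In the host tissue, nintedanib alone went with less vessel transcript, and the sprouting endothelium list was the clearest. The tip-cell list fell by a median of 0.72, with 16 of 19 members below 0 and 11 lower when adjusted over the list alone (adjusted p = 1.36e-13; adjusted p = 0.0241 with an estimated correlation, and 0.0126 with fry), and its score was -0.61 ± 0.12 (SD, n = 4) against a vehicle SD of 0.26. Members included the adhesion molecule Mcam (-1.06, SE 0.17, adjusted p = 0.0546 over all genes), the semaphorin receptor Plxnd1 (-1.11, SE 0.24), the basement membrane collagen Col4a1 (-0.72, SE 0.18) and the tip-cell ligand Apln (-0.97, SE 0.25). The endothelial list fell by 0.65 in 25 of 28 members, with 6 lower when adjusted over the list alone (adjusted p = 2.70e-14; adjusted p = 0.0904 with an estimated correlation), including the junction cadherin Cdh5 (-1.004, SE 0.25), Plvap (-0.86, SE 0.25), the receptor Tie1 (-1.11, SE 0.33) and the junction protein Esam (-0.69, SE 0.21). The endothelial score was 0.05 in the muscle-rich nintedanib 4 and -0.62 to -0.94 in the other 3 libraries. Pericyte genes fell by 0.38, with 1 of 15 lower when adjusted over the list alone (adjusted p = 0.000174; adjusted p = 0.0775 with an estimated correlation). Higd1b stood at -1.06 (SE 0.36). The pericyte median was -0.25 when scaled to the human plus mouse total. The receptor genes that nintedanib targets gave -0.49 (SE 0.20) for Kdr, -0.65 (SE 0.28) for Flt1, -0.50 (SE 0.20) for Pdgfrb, 0.38 (SE 0.28) for Pdgfra and -0.20 (SE 0.23) for Fgfr1, none past the threshold.

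Mouse-mapped neutrophil and hypoxia transcripts were higher with nintedanib, and mitotic transcripts were lower. The neutrophil list rose by 0.85, with 5 of 17 members higher when adjusted over the list alone (adjusted p = 6.11e-06; adjusted p = 0.119 with an estimated correlation), including the calprotectin genes S100a8 (1.84, SE 0.42) and S100a9 (1.46, SE 0.31) and the stefin Stfa2 (3.36, SE 0.74). Without nintedanib 3 its median was 0.28, and this library also had a skin score of 1.67 against -0.15 to 0.079 in the other 3, so skin and neutrophils were not separated there. The mouse hypoxia list rose by 0.52 in 21 of 22 members, with 1 higher when adjusted over the list alone (adjusted p = 2.55e-06; adjusted p = 0.375 with an estimated correlation). Angptl4 stood at 1.29 (SE 0.37) and the pyruvate dehydrogenase kinase Pdk1 at 0.88 (SE 0.30). The hypoxia median was 0.28 without vehicle 2 and 0.87 without nintedanib 4. Human reads mapped to the mouse genome stay open for this list in each comparison below. For the mouse mitosis, glycolysis and skin lists they were not tested as a source. Cell cycle and mitosis fell by 0.25, with 1 lower when adjusted over the list alone (adjusted p = 0.000523; adjusted p = 0.375 with an estimated correlation). Ube2c stood at -0.96 (SE 0.27) and Plk1 at -1.04 (SE 0.34). The list's call was lost without vehicle 2 (-0.099, adjusted p = 0.0600), and its median was -0.47 without vehicle 1, -0.50 without nintedanib 4 and -0.12 when scaled to the human plus mouse total. Against vehicle, list scores had an exact permutation p of 0.0286 for neutrophils, 0.2 for hypoxia and 0.286 for cell cycle and mitosis. Skeletal muscle transcripts, abundant in nintedanib 4, stood at 1.53 and adipocyte transcripts at -0.95 (adjusted p = 0.00885 and 0.00699; adjusted p = 0.719 and 0.666 with an estimated correlation). Muscle stood at -0.19, 2.70, 0.77 and 0.42 without nintedanib 4, vehicle 2, vehicle 3 or vehicle 4, and fat at 0.40, -1.43, -1.54 and -0.66 without vehicle 1, vehicle 3, vehicle 4 or nintedanib 1. With limma 0 of 17484 genes passed, 1051 had an unadjusted p under 0.05 where chance gives 874, edgeR and limma-voom gave 0 and DESeq2 gave 29. The count was 1 without vehicle 1 or alpelisib 3, 3 without combination 1, 1 with only the 2 groups compared, 2 with genes correlated between species left out, 2 with muscle and fat covariates and 3 without the 2 muscle-rich libraries.

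Alpelisib alone went with slightly lower vessel transcript in the host and with more skin and fat transcript, and these calls were lost without single libraries. The tip-cell list fell by 0.25 in 16 of 19 members (adjusted p = 0.00246; adjusted p = 0.428 with an estimated correlation). Mcam stood at -0.55 (SE 0.17) and Apln at -0.57 (SE 0.25). This list was no longer called without vehicle 4 (-0.077, adjusted p = 0.0535) or alpelisib 4 (-0.17, adjusted p = 0.0503), and stood at -0.015 (adjusted p = 0.0698) when scaled to the human plus mouse total and -0.15 with muscle and fat covariates. The endothelial list fell by 0.12 in 22 of 28 members (adjusted p = 0.00546; adjusted p = 0.555 with an estimated correlation). The call did not hold without alpelisib 1 (-0.058, adjusted p = 0.0978) or alpelisib 2 (-0.14, adjusted p = 0.0730), and the median was -0.064 without vehicle 4, -0.19 without alpelisib 3, -0.18 without alpelisib 4 and 0.099 when scaled to the human plus mouse total. The skin list rose by 1.31 in 16 of 17 members (adjusted p = 1.25e-06; adjusted p = 0.428 with an estimated correlation). The epithelial galectin Lgals7 stood at 3.91 (SE 1.21) and the cornified envelope gene Sprr1a at 3.44 (SE 1.14). Without alpelisib 1 the list stood at 0.036 (adjusted p = 0.279), Lgals7 at 2.55 and Sprr1a at 2.05, and without alpelisib 3 the list stood at 2.001. The adipocyte list rose by 1.15 in 15 of 16 members (adjusted p = 0.000633; adjusted p = 0.555 with an estimated correlation). The lipoprotein lipase gene Lpl stood at 1.05 (SE 0.50). As a list it lost its call without vehicle 4 (0.64, adjusted p = 0.0969) or alpelisib 4 (0.55, adjusted p = 0.266), and it stood at 2.62, 0.71, 0.76 and 2.55 without vehicle 1, vehicle 3, alpelisib 2 or alpelisib 3. Macrophage genes rose by 0.25 in 23 of 26 members (adjusted p = 0.00246; adjusted p = 0.428 with an estimated correlation). Trem2 stood at 0.38 (SE 0.19). The call was lost without alpelisib 3 (0.14, adjusted p = 0.135), and the median was 0.11 without vehicle 2 and 0.49 when scaled to the human plus mouse total. Collagens and matrix fell by 0.22 in 23 of 30 (adjusted p = 0.0069; adjusted p = 0.555 with an estimated correlation). The matrix protease Mmp14 stood at -0.58 (SE 0.26). The collagen call was lost without alpelisib 4 (-0.092, adjusted p = 0.200), and the median was -0.097 with muscle and fat covariates and 0.015 (adjusted p = 0.172) when scaled to the human plus mouse total.

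No member of these alpelisib lists passed when adjusted over the list alone. Kdr gave -0.41 (SE 0.20), Flt1 -0.83 (SE 0.28), Pdgfrb -0.16 (SE 0.20), Pdgfra -0.15 (SE 0.28) and Fgfr1 -0.27 (SE 0.23), and Pdgfrb and Pdgfra stood at 0.078 and 0.090 when scaled to the human plus mouse total, and Pdgfra at 0.029 without alpelisib 4. By limma 0 genes passed, 570 had an unadjusted p under 0.05 where chance gives 874, edgeR and limma-voom gave 0 and DESeq2 gave 1. The count of lists called was 14, but 9 without vehicle 1, 8 without vehicle 4 and 6 without alpelisib 4.

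Both drugs together went with lower vessel transcripts and higher lymphocyte transcripts in the host than vehicle. Of 9 mouse genes past the threshold, 8 fell. Mcam fell from a normalized value of 599 ± 68.5 (SD, n = 4) to 267 ± 55.1 (SD, n = 4), a log2 of -1.18 (SE 0.17, adjusted p = 0.0205). Notch4, an endothelial Notch receptor, fell from 151 ± 24.7 (SD, n = 4) to 49.5 ± 9.37 (SD, n = 4), a log2 of -1.60 (SE 0.26, adjusted p = 0.0232). The others that fell were the imprinted gene Mest (-1.65, SE 0.26, adjusted p = 0.0205), Trp53i11 of the tip-cell list (-2.07, SE 0.34, adjusted p = 0.0232), the Cdc42 effector Cdc42ep1 (-1.37, SE 0.24, adjusted p = 0.0409), the prion-like Prnd (-1.81, SE 0.32, adjusted p = 0.0409), the sulfotransferase Chst1 (-1.99, SE 0.36, adjusted p = 0.0463) and the homeobox gene Hoxc9 (-1.16, SE 0.20, adjusted p = 0.0409). Id2, an inhibitor of basic helix-loop-helix factors, rose by 1.38 (SE 0.22, adjusted p = 0.0205), and Id2 and Hoxc9 are named after their values were seen. The tool edgeR gave 12 genes, limma-voom 3 and DESeq2 82. In limma without the trend, or with only the 2 groups compared, 0 genes passed, and when scaled to the human plus mouse total 1 did (Id2, higher), with none of the 8 that fell. Replicate number as a block gave 3, a minimum value of 10 gave 15, leaving out genes correlated between species 14, muscle and fat covariates 20 and omission of the 2 muscle-rich libraries 24. The count was 0 without vehicle 3 or combination 3, 1 without vehicle 4, 3 without vehicle 1, 5 without nintedanib 2 or nintedanib 3, and 16 without alpelisib 3 or combination 1.

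All 28 endothelial genes were lower with both drugs, by a median of -0.66, and 13 were lower when adjusted over the list alone, with 0 over all genes (adjusted p = 2.55e-17; adjusted p = 0.105 with an estimated correlation). They included Esam (-1.12, SE 0.21, adjusted p = 0.0518), Cdh5 (-0.98, SE 0.25), Rasip1, needed for vessel lumens (-1.67, SE 0.39), and Mmrn2 (-1.04, SE 0.27). The tip-cell list fell by 0.65, with 11 of 19 members lower when adjusted over the list alone and 2 over all genes (adjusted p = 1.13e-13; adjusted p = 0.0236 with an estimated correlation, and 0.00685 with fry), with Col4a1 at -0.80 (SE 0.18) and Col4a2 at -1.12 (SE 0.24). Its score was -0.64 ± 0.014 (SD, n = 4). Pericytes fell by 0.40, with 2 of 15 lower when adjusted over the list alone and 1 over all genes (adjusted p = 0.00102; adjusted p = 0.131 with an estimated correlation), and smooth muscle and contractile genes fell by 0.44 with 0 lower when adjusted over the list alone (adjusted p = 0.000235; adjusted p = 0.190 with an estimated correlation). Acta2 stood at -0.63 (SE 0.24) and Actg2 at -1.02 (SE 0.35). Collagens and matrix fell by 0.31, with 1 lower when adjusted over the list alone (adjusted p = 0.00126; adjusted p = 0.486 with an estimated correlation). Mmp14 stood at -1.15 (SE 0.26) and Col11a1 at -1.16 (SE 0.36). The receptors Kdr, Flt1, Pdgfrb, Pdgfra and Fgfr1 gave -0.55 (SE 0.20), -0.61 (SE 0.28), -0.37 (SE 0.20), 0.28 (SE 0.28) and -0.33 (SE 0.23), none past the threshold, and Fgfr1 stood at 0.00067 when scaled to the human plus mouse total. That scaling gave medians of -0.33 for endothelial cells, -0.33 for tip cells, -0.080 for pericytes, -0.11 for smooth muscle and 0.019 for collagens, whose call it ended (adjusted p = 0.0835). The smooth muscle median was -0.69 without combination 1 and the collagen median -0.15 without combination 3.

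NK and T cell genes rose by 1.80 with both drugs, with 16 of 18 above 0 and 7 higher when adjusted over the list alone (adjusted p = 1.00e-08; adjusted p = 0.131 with an estimated correlation). They included the CD3 subunit genes Cd3d (2.998, SE 0.83) and Cd3e (3.51, SE 1.004), Cd2 (3.10, SE 0.86) and the cytokine receptor Il2rb (2.27, SE 0.66). Their list score was 1.56 ± 1.05 (SD, n = 4), from 0.45 to 2.55, and 2.04 in the muscle-rich nintedanib 4. Host tissue was not weighed as its source. Athymic nude mice lack a working thymus. Macrophage genes rose by 0.33 in 23 of 26 members (adjusted p = 8.46e-06; adjusted p = 0.131 with an estimated correlation). The lysozyme gene Lyz1 stood at 1.23 (SE 0.41) and the Fc receptor Fcgr1 at 0.59 (SE 0.21). Dendritic cell and MHC class II genes rose by 0.72 in 14 of 16 (adjusted p = 0.0002; adjusted p = 0.233 with an estimated correlation). Flt3 stood at 1.41 (SE 0.47) and H2-Ab1 at 0.73 (SE 0.30), and the median was 0.44 without combination 2. Hypoxia genes were higher in 22 of 22, by 0.53 (adjusted p = 5.59e-07; adjusted p = 0.279 with an estimated correlation). Pdk1 stood at 0.99 (SE 0.30) and Angptl4 at 1.16 (SE 0.37), and the median was 0.34 without vehicle 2. Glycolysis rose by 0.37 in 17 of 18 (adjusted p = 0.000495; adjusted p = 0.279 with an estimated correlation). Pgk1 stood at 0.69 (SE 0.22) and Ldha at 0.61 (SE 0.21). The glycolysis call was lost without vehicle 2 (0.098, adjusted p = 0.191). Cell cycle and mitosis fell by 0.43 in 19 of 22 (adjusted p = 6.92e-05; adjusted p = 0.279 with an estimated correlation). Ube2c stood at -0.86 (SE 0.27) and Plk1 at -1.04 (SE 0.34), and the median was -0.20 without vehicle 2. Scaled to the human plus mouse total, the medians were 0.66 for macrophages, 0.86 for hypoxia, 0.69 for glycolysis and -0.14 for cell cycle and mitosis. Of these 5 lists, from macrophages on, 0 members passed when adjusted over the list alone.

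**Figure D3:**
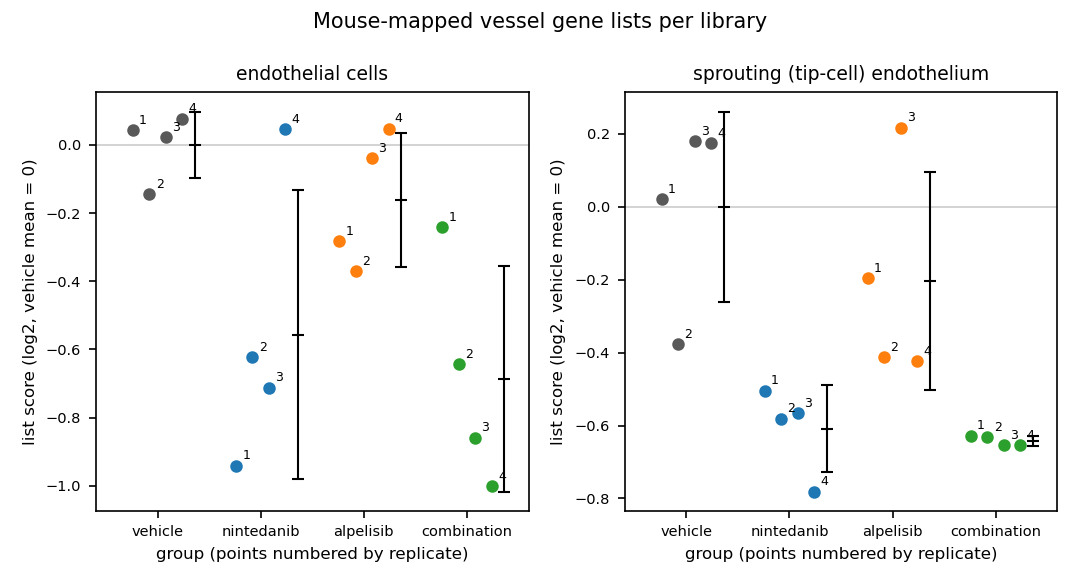
Scores of mouse-mapped gene lists in each library (log2, vehicle mean 0). Points are libraries numbered by replicate, and black bars give group means ± SD (n = 4). The 8 libraries with nintedanib had tip-cell scores between -0.50 and -0.78, against -0.38 to 0.18 with vehicle.

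Compared with nintedanib alone, the combination differed in 4 host lists, each of whose calls was lost without single libraries. NK and T cell genes rose by 0.63, with 2 of 18 higher when adjusted over the list alone (adjusted p = 0.00452; adjusted p = 0.903 with an estimated correlation). The list's call was lost without combination 2 (0.17, adjusted p = 0.253) or combination 3 (0.32, adjusted p = 0.132), and the median was 1.14, 0.95 and 1.33 without nintedanib 4, combination 1 or combination 4. Adipocyte genes rose by 0.95 (adjusted p = 0.016), neutrophil genes fell by 0.45 and collagens fell by 0.27 (adjusted p = 0.0119 each), with 0 members past the threshold when adjusted over the list alone and adjusted p = 0.903 with an estimated correlation for each. The adipocyte call was lost without combination 1, combination 2 (0.48), nintedanib 1 or nintedanib 3, and the median was 1.49 without combination 4. The neutrophil call was lost without nintedanib 3 (-0.18), combination 2 or combination 4, and stood at -0.71 without combination 3 and -0.78 without nintedanib 4. The collagen call was lost without nintedanib 1 (-0.094), nintedanib 3, combination 1 or combination 3, and stood at -0.51 without nintedanib 4. In limma, 0 genes passed, 898 had an unadjusted p under 0.05, and edgeR, limma-voom and DESeq2 gave 0. The count of lists called was 4, but 1 without nintedanib 3, 2 without combination 2 or combination 3, and 8 without combination 1.

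Compared with alpelisib alone, the combination had less endothelial and tip-cell transcript in the host. It also had less mouse-mapped mitotic transcript and more mouse-mapped hypoxia and glycolysis transcript. Endothelial genes fell by 0.53, with 7 of 28 lower when adjusted over the list alone (adjusted p = 8.45e-11), and tip-cell genes fell by 0.61, with 10 of 19 lower and 1 higher when adjusted over the list alone (adjusted p = 2.99e-08). Mouse cell cycle and mitosis genes fell by 0.69, with 6 of 22 lower when adjusted over the list alone (adjusted p = 4.64e-11), glycolysis rose by 0.46, with 3 of 18 higher (adjusted p = 8.39e-08), and NK and T cell genes rose by 1.53, with 1 of 18 higher (adjusted p = 6.56e-09). These 5 lists had an adjusted p = 0.155 with an estimated correlation. Hypoxia genes were higher in 22 of 22, by 0.64, with 0 past the threshold when adjusted over the list alone (adjusted p = 8.57e-10; adjusted p = 0.280 with an estimated correlation). Adipocyte and skin lists stood at -1.36 and -1.14 (adjusted p = 0.000848 and 0.000117; adjusted p = 0.518 and 0.482 with an estimated correlation), beside the high scores of alpelisib 1, 2 and 4. The adipocyte call was lost without alpelisib 2 (-0.88), alpelisib 4 (-0.51) or combination 4 (-0.83), and stood at -2.59 without alpelisib 3. The skin list stood at 0.125 (adjusted p = 0.967) without alpelisib 1 and -1.72 without alpelisib 4. The limma count was 0, 1007 had an unadjusted p under 0.05, edgeR and limma-voom gave 0 and DESeq2 gave 25. The count was 1 without combination 1.

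In the host, the interaction did not pass the test for the endothelial list (-0.01, adjusted p = 0.504) or the tip-cell list (0.23, adjusted p = 0.132). Neutrophil genes stood at -1.02 in 13 of 17 members (adjusted p = 0.000588; adjusted p = 0.471 with an estimated correlation), but at -0.26 without nintedanib 3 and -0.66 without combination 4. The skin list stood at -1.23 in 16 of 17 (adjusted p = 0.00119; adjusted p = 0.755 with an estimated correlation) and at 0.052 and -2.02 without alpelisib 1 or alpelisib 3. No member of either passed when adjusted over the list alone. The 5 genes with the smallest p were Metrn (-1.71, SE 0.39), Dnm3os (2.74, SE 0.62), Map4k2 (2.75, SE 0.69), Tmem40 (-3.58, SE 0.90) and Oscar (3.09, SE 0.79), each with an adjusted p of 1. With limma 0 genes passed, 545 had an unadjusted p under 0.05 where chance gives 874, and edgeR, limma-voom and DESeq2 gave 0. The count of lists called was 7, but 1 without alpelisib 1, 2 without vehicle 3 or vehicle 4, 3 without combination 3, 4 without alpelisib 2, alpelisib 4 or combination 2, and 11 without alpelisib 3.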

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

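The tests of host muscle and fat, of scaling and of each drug as an explanation were chosen only after the results were seen, and those of mouse skin reads, library depth, human reads in the mouse table and other splits of the planned comparisons before.

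Of 132 group values examined, 12 held a library far from the other 3 of its group, where chance gives about 1 in 20. The human interferon response score was 0.69 in alpelisib 3 against 0.19 to 0.25 in the others. The human NF-kB target score was 1.24 in nintedanib 3 against 0.020 to 0.20, and the human glycolysis score -0.14 in nintedanib 4 against 0.16 to 0.20. The human mesenchymal score was 0.35 in alpelisib 3 against -0.24 to -0.14. The mouse skin score was 1.67 in nintedanib 3 against -0.15 to 0.079, and 5.63 in alpelisib 1 against 0.14 to 0.72. The NK and T cell score was 2.04 in nintedanib 4 against 0.14 to 0.36, and the skeletal muscle score was 6.61 in nintedanib 4 against -0.41 to -0.024. In vehicle 2 mouse glycolysis was -0.48 against 0.11 to 0.21 and fibroblasts -0.32 against 0.079 to 0.14, in vehicle 1 the dendritic cell score was 0.39 against -0.17 to -0.11, and in combination 3 the mouse interferon score was 0.85 against -0.27 to -0.17.

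In 12 lists the effect of 1 drug differed with the presence of the other by the preset-correlation interaction test. The human medians (log2) were -1.07 for squamous differentiation, -0.30 for interferon response, 0.28 for glycolysis, 0.23 for DNA replication and 0.20 for oxidative phosphorylation. The mouse medians were -1.02 for neutrophils, -1.23 for skin, 0.29 for pericytes, 0.28 for fibroblasts, 0.50 for NK and T cells, -0.21 for cell cycle and mitosis and 0.18 for interferon response. Of these, the human interferon median was -0.14 without alpelisib 3, and the mouse medians were -0.26 for neutrophils without nintedanib 3 and 0.052 for skin without alpelisib 1. Single libraries left out ended the calls of the other lists except squamous differentiation. The lowest medians reached were 0.10 for DNA replication (without combination 1), 0.16 for human glycolysis (vehicle 3), 0.23 for pericytes (vehicle 4), 0.096 for fibroblasts (nintedanib 4), 0.12 for NK and T cells (combination 2) and -0.012 for mouse interferon (combination 3), while cell cycle and mitosis came to -0.10 (nintedanib 4). Oxidative phosphorylation lost its call without combination 1 (0.16, adjusted p = 0.245), among others. None of the 12 was called with an estimated correlation.

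Lower sprouting endothelium transcripts in the nintedanib groups were weighed against host tissue and scaling. With muscle and fat scores as covariates the averaged tip-cell difference was -0.536 (95% interval -0.747 to -0.326), beside -0.523 (-0.750 to -0.297) without, which argues against dilution by muscle and fat. Scaled to the human plus mouse total it was -0.413 (-0.692 to -0.134), which argues against scaling as the whole cause. For the endothelial list the covariates gave -0.542 (-0.907 to -0.177), but the joint scaling gave -0.433 (-0.989 to 0.123), an interval that reaches 0, so scaling stays open there. Nintedanib treatment remains a candidate explanation, with an exact permutation p of 0.000408 for tip-cell genes, the smallest that 4900 regroupings can give, and 0.00571 for endothelial genes.

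The human squamous differentiation list was higher with each drug alone but not with both. Mouse skin reads in the human table were argued against, since mouse-mapped reads of the 24 shared symbols came to at most 1.86 per 100 human-mapped reads. Depth was argued against, since the interaction of the list score was -0.9997 (95% interval -1.80 to -0.199) with human depth as a covariate. The drug combination stays a candidate, with a permutation p of 0.0103 over 100000 draws of all group labels. That p was not adjusted for the choice of this list, which had the largest median interaction of the 22. Shuffling all labels also removes the single-drug differences, so it does not test additivity alone. Against vehicle the list score had an exact permutation p of 0.0571 with nintedanib, 0.114 with alpelisib and 0.714 with both. Chance could not be excluded for the count of interaction lists called (5), since 63 of 100 regroupings gave as many and the highest other gave 14. The 5 became 8 without vehicle 1, vehicle 4, alpelisib 4 or combination 3, 9 without nintedanib 1 or combination 1, 3 without alpelisib 1 and 2 without combination 2.

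The mouse hypoxia list was higher in the nintedanib groups, as was the human one. Human reads mapped to the mouse genome cannot be told apart from host transcripts, since the list's mouse-over-human ratio was 30.0%, or 9.51 times the 10th percentile of 3.15% over 3148 shared symbols, between the bounds of 3 and 10 set for the test. Muscle and fat were argued against, since the averaged difference was 0.562 (95% interval 0.216 to 0.907) with both as covariates, beside 0.587 (0.0601 to 1.11) without. Nintedanib treatment may account for it, with an exact permutation p of 0.0298, not adjusted for choosing this list and comparison. Against vehicle the exact permutation p was 0.2 with nintedanib and 0.114 with both.

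Regroupings of the same libraries were fitted for every count, and chance could not be excluded for any count above 0 of a planned comparison. For the 1 human gene of combination against alpelisib, 2 of 35 splits gave as many, with 4 the highest other. For the 9 mouse genes of combination against vehicle, 2 of 35 splits gave as many, and the other gave 307, with vehicle 1 and combination 1, 2 and 3 on the same side. A real count of 0 genes is reached by every split (35 of 35, or 100 of 100 for the interaction), so for it the splits decide nothing about chance. The highest other counts there were 2, 26, 3, 3 and 1 in human nintedanib, alpelisib and combination against vehicle, combination against nintedanib and the interaction, and 0, 65, 227, 16 and 102 in mouse nintedanib and alpelisib against vehicle, the combination against nintedanib and alpelisib, and the interaction. The 307 beside a real count of 9, and the 227, 102 and 65 beside real counts of 0, point to a structure of the samples other than the treatment. In the 307 split, the side holding vehicle 1 had the higher mouse shares of reads (24.1% to 31.5% against 19.3% to 23.3%). In the 227 split, nintedanib 4 with combination 1, 2 and 3 also had the higher shares (27.0% to 34.0% against 20.5% to 24.9%). In the 65 split, vehicle 1 with alpelisib 1, 2 and 4 had the higher adipocyte scores (0.54 to 3.92 against -2.10 to -0.32). Whether these orders account for the counts was not tested.

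For lists called, 9, 12, 4, 33 and 3 of 35 human splits reached the real counts of 10, 8, 11, 2 and 11, in the order nintedanib, alpelisib and combination against vehicle, then combination against nintedanib and against alpelisib. The highest others were 12, 12, 12, 11 and 12. In the mouse, 3, 6, 6, 31 and 5 of 35 splits reached the real 15, 14, 12, 4 and 12 in the same order, with 16, 16, 16, 14 and 15 the highest others. Of these counts, the human ones became 5 for alpelisib against vehicle without vehicle 3, 6 for combination against vehicle without combination 4, and for combination against nintedanib 4 without nintedanib 2 or nintedanib 3 and 5 without combination 1 or combination 4. The mouse counts ran from 6 to 14 for alpelisib against vehicle and 1 to 8 for combination against nintedanib. For the mouse interaction (7 lists) 69 of 100 regroupings did, with 15 the highest other. That count ran from 1 (without alpelisib 1) to 11 (without alpelisib 3).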

How the results depend on the processing

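Tests on recovered reads, joint scaling, the minimum of 10, the omission of muscle-rich libraries, the covariates and the averaged effects were chosen only after the data were seen, and the others were planned. The causes of the changes given here were not tested, except that fewer samples or fewer genes enter where libraries or genes are left out. Among alternatives other than leaving out 1 library, 214 counts stayed within 1.5 times the main one and 100 did not, and 406 list medians kept direction and call, 193 lost the call, 1 gained it and 10 changed sign. For the genes named, 1994 values kept direction and call, 105 lost the call, 59 gained it and 8 changed sign.

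Quantile normalization gave 0 human genes for combination against alpelisib, FGFR1 at -0.12 for combination against vehicle, and 4 and 3 human lists for combination against nintedanib and for averaged alpelisib. Without the trend limma gave 1, 2, 2 and 1 human genes for nintedanib against vehicle, combination against nintedanib, the interaction and averaged alpelisib, and 0 and 4 mouse genes for combination against vehicle and averaged nintedanib. With no filter on low values the human counts were 1, 1 and 0 for nintedanib against vehicle, combination against nintedanib and combination against alpelisib, and a pseudocount of 0.1 gave 0 for the last. With replicate number as a block the human counts were 8, 1, 0 and 3 for nintedanib and alpelisib against vehicle, combination against alpelisib and the interaction, the mouse count was 3 for combination against vehicle, and 8 and 5 human lists were called for the interaction and averaged alpelisib. Leaving out genes correlated between species gave 2 and 14 mouse genes for nintedanib and combination against vehicle. The labels do not say what a replicate number marks. Over 24 same-numbered pairs per species, 2 human and 3 mouse pairs had a correlation of residuals over 0.1, and 4 of 16 human and 1 of 16 mouse libraries were closest to 1 with their own number. With only the groups compared the human counts were 89, 2 and 0 for nintedanib against vehicle, alpelisib against vehicle and combination against alpelisib, and the mouse counts 1 and 0 for nintedanib and combination against vehicle.

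On recovered reads edgeR gave 0 genes for human combination against alpelisib, and FGFR1 at -0.0073 for combination against vehicle. DESeq2 gave 74, 1, 14, 2, 17 and 10 human genes in the order of the 6 comparisons and 142 for averaged nintedanib, with FGFR1 at -0.0076, and 29, 1, 82 and 25 mouse genes for nintedanib, alpelisib and combination against vehicle and combination against alpelisib, and 157 for averaged nintedanib. For limma-voom the counts were 0 for human combination against alpelisib, 3 for mouse combination against vehicle and 10 for averaged nintedanib, with FGFR2 at 0.018 in combination against vehicle. A minimum of 10 gave 0 and 15 for human combination against alpelisib and mouse combination against vehicle.

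Scaling to the human plus mouse total took the median of all mouse genes (log2) from 0.020 to 0.14, 0.015 to 0.23 and 0.030 to 0.32 for nintedanib, alpelisib and combination against vehicle, and to 0.18 for combination against nintedanib, 0.12 for averaged nintedanib and 0.21 for averaged alpelisib. It gave 27 human genes for averaged nintedanib, 1 and 3 mouse genes for combination against vehicle and averaged nintedanib, 6 human lists for averaged alpelisib, and 6, 4 and 5 mouse lists for alpelisib against vehicle, the interaction and averaged alpelisib. Alpelisib against vehicle then read 0.078 for Pdgfrb, 0.090 for Pdgfra, 0.015 for collagens and 0.099 for endothelial cells, combination against vehicle 0.00067 for Fgfr1 and 0.019 for collagens, averaged alpelisib 0.022 for collagens, and combination against nintedanib 0.17 for tip cells. Omitting nintedanib 4 and combination 1 gave 8, 14 and 74 human genes for nintedanib against vehicle, combination against alpelisib and averaged nintedanib, with FGFR3 at 0.056 in combination against vehicle, 4 and 4 human lists for combination against nintedanib and averaged alpelisib, 3, 24, 1 and 54 mouse genes for nintedanib and combination against vehicle, combination against alpelisib and averaged nintedanib, 7 mouse lists for combination against nintedanib, and skeletal muscle at -0.19 in nintedanib against vehicle. Muscle and fat covariates gave 2, 20, 1, 2 and 9 mouse genes for nintedanib and combination against vehicle, combination against alpelisib, the interaction and averaged nintedanib, 5 mouse lists for averaged alpelisib, skeletal muscle at -0.020 and adipocytes at 0.11 in nintedanib against vehicle, adipocytes at -0.0060 in alpelisib against vehicle and tip cells at 0.059 in combination against nintedanib.

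With an estimated correlation 0 human lists were called in any of the 8 comparisons, and in the mouse 1 each for nintedanib against vehicle, combination against vehicle and averaged nintedanib and 0 for the other 5. With fry the counts were 0 in human and 1, 1 and 2 for the same 3 mouse comparisons, with 0 for the other 5.

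Leaving out each library in turn, human gene counts ranged from 0 to 4 for nintedanib against vehicle, 0 to 1 (without combination 1 or 2) for alpelisib against vehicle, 0 to 136 (without combination 4) for combination against nintedanib, 0 to 1 for combination against alpelisib, 0 to 8 (without combination 2) for the interaction and 0 to 11 (without nintedanib 4) for averaged nintedanib. Mouse gene counts ranged from 0 to 3 (without combination 1) for nintedanib against vehicle, 0 (without vehicle 3 or combination 3) to 16 (without alpelisib 3 or combination 1) for combination against vehicle, 0 to 1 (without combination 1) for combination against alpelisib and 9 to 31 (without combination 1) for averaged nintedanib. Human list counts ranged from 5 to 10 for alpelisib against vehicle, 6 to 13 for combination against vehicle, 2 to 5 for combination against nintedanib, 2 to 9 for the interaction and 1 to 6 for averaged alpelisib, and mouse list counts from 6 to 14 for alpelisib against vehicle, 1 to 8 for combination against nintedanib and 1 to 11 for the interaction. FGFR2 ranged from -0.21 to 0.0096 (without vehicle 2) in nintedanib against vehicle and PIK3CA from -0.055 (without vehicle 1) to 0.21 in alpelisib against vehicle. In combination against vehicle PIK3CA ranged from -0.16 (without combination 4) to 0.52 and FGFR1 from -0.15 (without vehicle 1) to 0.41. There FGFR2 ranged from -0.098 to 0.12 (without combination 3) and FGFR3 from -0.30 to 0.056 (without combination 1). The squamous list ranged there from -0.00034 (without combination 2) to 0.36 (without combination 1, where it was called, as without vehicle 2). Mouse Pdgfra ranged from -0.33 to 0.029 (without alpelisib 4) in alpelisib against vehicle, tip cells from -0.11 to 0.093 (without combination 1, with 0.032 without nintedanib 2 and 0.0070 without combination 3) in combination against nintedanib, and the skin list from -2.02 to 0.052 (without alpelisib 1) in the interaction and -1.72 (without alpelisib 4) to 0.125 (without alpelisib 1) in combination against alpelisib. In nintedanib against vehicle skeletal muscle ranged from -0.19 (without nintedanib 4) to 2.70 (without vehicle 2) and adipocytes from -1.54 (without vehicle 4) to 0.40 (without vehicle 1), and mouse interferon response in the interaction ranged from -0.012 (without combination 3) to 0.30 (without combination 4). The mouse share of reads differed from vehicle by 1.155 (without nintedanib 4) to 5.035 percentage points with nintedanib, 2.80 to 5.53 points (without alpelisib 1) with alpelisib and 3.80 to 7.47 points (without combination 4) with both drugs. For the lower simulated recovery in mouse, depth was not told apart from the spread between libraries.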

Other observations

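The drug effects averaged over both levels of the other drug, 8 libraries against 8, and the genes named from them were chosen only after the data were seen, while the gene lists were not.

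Averaged over alpelisib, nintedanib went with lower transcript of a set of vessel genes in the host, none of which passed the threshold when scaled to the human plus mouse total. With limma 17 mouse genes passed the threshold, of which 5 were higher and 12 lower, with edgeR 20, limma-voom 10 and DESeq2 157. The count was 4 in limma without the trend, 3 (all higher, with 0 lower) when scaled to the human plus mouse total, 9 with muscle and fat scores as covariates and 54 without the 2 muscle-rich libraries. Among those lower were the Notch receptor Notch4 (-1.29, SE 0.19, adjusted p = 0.0057, with 7 of the 8 treated libraries below all others), Mcam (-0.85, SE 0.12, adjusted p = 0.0057, 8 of 8), the junction genes Esam (-0.82, adjusted p = 0.0343, 6 of 8) and Cdh5 (-0.91, adjusted p = 0.0479, 7 of 8), the basement membrane collagen Col4a1 (-0.68, adjusted p = 0.0418, 8 of 8) and the semaphorin receptor Plxnd1 (-0.88, adjusted p = 0.0479, 6 of 8). Also lower were Mest (-1.20), Trp53i11 (-1.58), Cdc42ep1 (-1.10), Chst1 (-1.50), Hoxc9 (-0.79) and the chloride channel Ano1 (-1.50). Higher were Id2 (1.16, SE 0.15, adjusted p = 0.00493, 8 of 8), the B cell chemokine Cxcl13 (2.41, SE 0.36, 7 of 8), Cilp of cartilage matrix (1.38, SE 0.21, 7 of 8), the complex I gene Ndufs4 (0.70, SE 0.13, 8 of 8) and Gm5483 (3.23, 6 of 8). Of 16 omissions of 1 library, 12 ended the call of Cdh5, 12 of Col4a1, 11 of Plxnd1, 9 of Esam and 14 of Ndufs4. Over all alternatives that ended a call, the adjusted p ran from 0.0596 to 0.336 for Cdh5, 0.0629 to 0.352 for Col4a1, 0.0596 to 0.372 for Plxnd1, 0.0606 to 0.362 for Esam and 0.0507 to 0.281 for Ndufs4. Ano1, Chst1 and Hoxc9 also lost their calls without vehicle 1, vehicle 3, nintedanib 3, alpelisib 2, alpelisib 4 or combination 3, among others. The call of Notch4 was lost when scaled to the human plus mouse total (adjusted p = 0.229), as were those of Mcam (0.256) and Mest (0.229), which limma without the trend also left uncalled (0.0621 each). That scaling also ended the calls of Trp53i11 (0.129), Cdc42ep1 (0.281) and Cilp (0.0747), limma without the trend those of Cxcl13 (0.0621), Trp53i11 (0.0865) and Cilp (0.087), limma-voom those of Cxcl13 (0.0802) and Gm5483 (0.0525), and muscle and fat covariates that of Cdc42ep1 (0.0544). The tip-cell list fell by 0.68, with 13 of 19 lower and 1 higher when adjusted over the list alone and 4 lower over all genes (adjusted p = 1.26e-14; adjusted p = 0.018 with an estimated correlation, and 0.00166 with fry). The endothelial list fell by 0.50, with 16 of 28 lower when adjusted over the list alone and 2 over all genes (adjusted p = 2.97e-18; adjusted p = 0.0896 with an estimated correlation, and 0.0321 with fry). Of 100 regroupings only the real one gave as many as 17 genes (1 of 100), and the highest other gave 1. That argues against chance for the 17 genes but does not exclude it. The 16 lists called were reached by 4 of 100 regroupings, with 18 the highest other. A share under 5 in 100 says less where, as here, 32 counts were examined and the comparison was chosen after the data were seen. The count of genes was 9 without vehicle 1, nintedanib 3, alpelisib 2, alpelisib 4 or combination 3, 10 without vehicle 3 or nintedanib 2, and 31 without combination 1.

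In the same averaged comparison, all 22 hypoxia genes of the tumour cells were higher, by a median of 0.67, and 16 were higher when adjusted over the list alone (adjusted p = 1.67e-13; adjusted p = 0.200 with an estimated correlation). Human antigen presentation fell by 0.39 with 11 of 21 lower, oxidative phosphorylation by 0.28 with 9 of 23 lower and cell cycle and mitosis by 0.23 with 7 of 22 lower when adjusted over the list alone (adjusted p = 6.92e-08, 9.94e-08 and 2.74e-07; adjusted p = 0.200 with an estimated correlation for each). The antigen presentation score was 0.26 in nintedanib 4 and 0.24 in combination 1, the 2 muscle-rich libraries, above all 4 vehicle libraries, and -0.27 to -0.69 in the other 6 treated ones. In the mouse table, 22 of 22 hypoxia genes were higher, by 0.59, with 6 higher when adjusted over the list alone, NK and T cell genes rose by 1.33 (1.055 without nintedanib 4), with 7 of 18 higher, and cell cycle and mitosis fell by 0.51, with 7 of 22 lower (adjusted p = 4.73e-12, 7.73e-08 and 1.05e-10; adjusted p = 0.158 with an estimated correlation for each). With limma 0 human genes passed, 2501 had an unadjusted p under 0.05, edgeR and limma-voom gave 0 and DESeq2 gave 142. The human count was 3 without vehicle 3, 11 without nintedanib 4 and 1 without alpelisib 3, 27 when scaled to the human plus mouse total and 74 without the 2 muscle-rich libraries. Chance could not be excluded for the 10 human lists (27 of 100 regroupings, highest other 13). The count of 0 human genes is reached by every regrouping (100 of 100, highest other 5), which decides nothing about chance.

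Averaged over nintedanib, alpelisib gave 0 genes past the threshold in either species by limma, edgeR, limma-voom or DESeq2, with 732 human and 923 mouse genes at an unadjusted p under 0.05. It gave 1 human list, cell cycle and mitosis (-0.25, adjusted p = 1.53e-06), and 9 mouse lists, among them collagens and matrix (-0.19, adjusted p = 0.000395) and macrophages (0.23, adjusted p = 0.00153). Collagens stood at -0.33 without nintedanib 4 and 0.022 when scaled to the human plus mouse total, and macrophages at 0.15, 0.15 and 0.13 without vehicle 2, alpelisib 3 or combination 2. None was called with an estimated correlation. Human lists numbered 2 to 6 without any 1 library except vehicle 1, nintedanib 3 or alpelisib 1. Chance could not be excluded for the human list (98 of 100, highest other 12) or the mouse lists (40 of 100, highest other 18). Every regrouping reached the 0 genes of each species (100 of 100), which decides nothing about chance. The highest others were 2 in human and 78 in mouse, and the 78 points to a structure of the samples.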
